A study of Mus musculus with 6 samples.

How the data were processed

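RNA was measured in 6 libraries of P14 CD8+ T cells from C57BL/6 mice, 3 sorted from B16-GP33-41 tumors and 3 sorted from spleens. Per the labels' protocols, tumors and spleens were both mashed, tumor leukocytes alone were recovered over Percoll before sorting, and spleens of the same tumor-bearing mice gave the control cells. Libraries were built with a low-input cDNA kit and a stranded library kit, pooled 6 to a lane and read on a HiSeq 2000 as single reads of 50 bp, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.3, featureCounts and the mm10 genome. The version of featureCounts, the gene annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here.

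The deposited values were whole-number counts per gene, which the authors made from the reads and which carry no normalization. The table held 55335 gene identifiers and no row without a gene. Symbols and mm10 coordinates came from GENCODE release M21 or, for symbols it lacked, a reference list of gene names. A symbol was found for 55154 identifiers, and 54587 matched the release with their version number. The 181 identifiers without a symbol held at most 0.0514% of the counts of any library. Each of the 6 columns carried the title or code of 1 sample. Total counts ranged from 35095261 to 38263483, and 35231 genes had a count in some library. A count of 0 in a library allows up to 3 counts, which is at most 0.0855 CPM (a count divided by the library total and scaled as usual). Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

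Libraries were grouped by the tissue in their titles. Before averaging, the counts of each pair were compared by chi-square. The statistic per degree of freedom was 2.19 to 3.48 between spleen libraries, 9.06 to 33.2 between tumor libraries and 244 to 274 across tissues. Every pair differed by more than counting noise, so no library is a copy of another, and n is the 3 libraries of each tissue. Separate preparations of 1 pool would also exceed that noise. The biological coefficient of variation, fitted for each tissue over 15663 genes, was 10.4% in tumor and 3.20% in spleen. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical. Nor do they say whether equal replicate numbers mark 1 mouse. Deviations of equal-numbered tumor and spleen libraries correlated at -0.0008, 0.016 and 0.0024, all under the 0.1 asked for pairing. This does not exclude shared mice, and the replicate number was used only in an alternative.

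Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, tissue as the factor). Low counts were filtered with filterByExpr at a minimum count of 10 and a minimum total of 15, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are tumor over spleen on the log2 scale. SE is an approximate standard error, the absolute log2 fold change divided by the square root of its F statistic. CPM values are counts over the library total, given as mean ± SD with n = 3. A fold against a tissue with 0 counts in all libraries was computed against 3 counts over that tissue and is given as a lower bound. With 1 to 3 counts over a tissue, the ratio of shares is given with its exact binomial interval. Shares of counts were compared with the two-sided exact permutation test (SciPy 1.17.1), whose smallest possible p for 3 against 3 is 0.1.

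The design, the 38 gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The lists held 762 entries from textbook knowledge of CD8+ T cells, of metabolism and stress, and of other cell types in tumor and spleen. The table held 761 of them, and 730 were tested. Of the tested genes, 7 belonged to more than 1 list (Ccr7, Apoe, Tyrobp, Eomes, Rora, Gata3 and Il1rl1). Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data.

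Genes were named by 4 rules. Within each list, these were the 2 members with the smallest p in each direction. All members of the inhibitory receptor, transcription factor, naive and memory, and cytotoxic lists could be named. Across all genes, the 10 largest rises and 10 largest falls were named, if the adjusted p passed, the mean was at least 10 CPM and the tissues did not overlap. Gene models without a symbol, receptor and immunoglobulin segments and pseudogenes were left out of that ranking. Of each list of another cell type, the member with the highest CPM in each tissue was named. Members given to spell out a count of 5 or fewer, and single genes said to be so chosen, were picked after their values were seen. Some genes that these rules pick are not reported here.

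The procedure was tested on 5 simulated tables made from the real means and library sizes, with 200 changed genes in each. It recovered 21.0% of genes changed 1.25-fold, 66.0% of those changed 1.5-fold, 85.8% of those changed 2-fold and 98.0% of those changed 4-fold. Of the calls, 7.95% were false, above the nominal 5%. The simulation used 1 dispersion per gene for both tissues and few changed genes, whereas 70.7% of the real genes were called. Its rates therefore do not give the recovery or the false share in the real data.

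Alternatives were other scalings (DESeq2 size factors, upper quartile, library size), no filter, a mean of at least 5 CPM, a replicate block, each library left out, DESeq2 1.42.0, limma-voom, a test against a 2-fold change, a gene set without other-cell, mitochondrial, ribosomal and receptor genes, and other list tests (estimated correlation, fry). Added after seeing the data were the spleen libraries summed into 1 sample, a correction for GC content and exonic length, and limma-voom with a weight per tissue. Figures were drawn with matplotlib 3.10.9.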

Results

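CD8+ T cells of the P14 line carry a transgenic receptor for the GP33-41 peptide. These cells were transferred into mice on day 11 after implantation of B16 melanoma cells that express this peptide, and the donor cells were later sorted from tumor and from spleen. The comparison asks how the transcripts of one antigen-specific T cell population differ between the tumor, where its antigen is made, and the spleen of tumor-bearing mice. Gene counts were analysed for 3 tumor libraries, with totals of 36464221, 38263483 and 36198681, and 3 spleen libraries, with totals of 36565214, 37650999 and 35095261. Totals did not differ between tissues beyond their spread (two-sided exact permutation p = 0.7, n = 3 per tissue).

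P14 cells from tumor carried higher transcript levels of 11 of 18 inhibitory receptor and exhaustion genes, 21 of 28 effector and cytokine genes and the NR4A transcription factors than those from spleen. Several chemokine genes were higher, while Ccl5 was lower (-1.76 on the log2 scale). Pdcd1, which encodes the inhibitory receptor PD-1, was at 242 ± 4.14 CPM in tumor and 7.52 ± 0.691 CPM in spleen (SD, n = 3 each). The chemokine gene Ccl3 was at 372 ± 31.4 CPM in tumor and 1.63 ± 0.0279 CPM in spleen. Genes of glycolysis, the hypoxia response, serine metabolism and DNA replication were also higher in tumor. Lower in tumor were genes of naive and memory T cells, including Klf2 and S1pr1, interferon response genes, the 13 protein genes of the mitochondrial genome, and genes of B cells and myeloid cells. With an estimated correlation the mitochondrial list was not called (adjusted p = 0.39).

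Of 19783 genes tested, 6890 were higher and 7093 lower in tumor (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). A difference of at least 4-fold was found for 515 of the higher and 1140 of the lower genes. The tissues did not overlap for 14744 genes, 74.5% of those tested, where chance gives 10%. Against a null of a 2-fold change, 1161 genes were higher and 1864 lower. The higher genes thus made up 38.4% of calls in place of 49.3%. Among the lower genes of that test were 16 of 16 B cell and 17 of 20 macrophage markers, so not all need be changes in P14 cells. Codes in the sample descriptions share one ending in all tumor libraries and another in all spleen libraries. If this marks a batch, batch and tissue cannot be told apart.

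By size, the largest rise belonged to Rgs16, a regulator of G protein signalling, at 239 ± 15.7 CPM in tumor and 0.543 ± 0.172 CPM in spleen (448-fold, log2 fold change 8.81, SE 0.14, adjusted p = 2.5e-12). The chemokine genes Ccl3 (233-fold), Xcl1 (217-fold), Ccl4 (189-fold) and Ccl1 (186-fold) followed. The other rises were in Spry1, an inhibitor of receptor kinase signalling (89.3-fold), the nuclear receptor gene Nr4a2 (75.5-fold), the heat shock genes Hspa1a (73.1-fold) and Hspa1b (65.3-fold), and Utf1 (63.4-fold). Among the 10 largest falls, 5 were in the fixed B and plasma cell list. Cr2, a complement receptor of B cells, had 0 counts in the tumor libraries and 30.1 ± 2.37 CPM in spleen, at least 1114-fold lower in tumor. Blk (-9.99 on the log2 scale), Ms4a1 (-8.56) and Fcer2a (-8.05), all B cell genes, fell too. Blk had 2 counts over the tumor libraries and 2425 over spleen (1230-fold, 95% counting interval 340 to 10166). Outside that list, the falls were in Fcmr, the receptor for IgM (-9.35), Slc40a1, the iron exporter ferroportin (-8.66), Ly6d (-8.55), and the transcription factor genes Spib (-8.08) and Mef2c (-7.91). The list is not complete, so a gene outside it can still come from B cells or myeloid cells, whose markers were lower in the same libraries. Leaving out 1 tumor library moved 3 of the 10 falls by over 1.5 times, to -9.14 for Ms4a1 without replicate 3, -9.36 for Ly6d without replicate 1 and -9.11 for Mef2c without replicate 2. Rgs16, Xcl1, Spry1, Hspa1a and Ms4a1 each overlap 1 gene model on the opposite strand, and the strand setting of the counting is not given in the sources used here. Hspa1a and Hspa1b are near-identical copies, and their separate values are uncertain.

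In mm10, Pdcd1 (ENSMUSG00000026285.7) lies on chromosome 1 at 94038305 to 94052553 and Ccl3 (ENSMUSG00000000982.5) on chromosome 11 at 83647844 to 83649355. Rgs16 (ENSMUSG00000026475.7) lies on chromosome 1 at 153740349 to 153745468 and Klf2 (ENSMUSG00000055148.7) on chromosome 8 at 72319033 to 72321656. Values are counts over the annotated gene as deposited.

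Of the 38 fixed lists, 17 were higher and 11 lower in tumor by camera with a preset correlation, and 10 and 8 with an estimated correlation. Calls that held with an estimated correlation were weaker, with adjusted p from 0.013 (B cell and macrophage lists) to 0.049 (glycolysis). By fry, which does not set members against other genes, 7 lists without a camera call passed: residency, cytokine receptors, fatty acid oxidation, fatty acid synthesis, CD4 and related T cells, NK, and fibroblast and endothelial genes (adjusted p from 5.0e-05 to 0.043). Gene counts adjusted over the list alone equalled those over all genes tested, except that glycolysis had 1 lower member when adjusted over the list alone (Pfkfb4).

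**Figure D1:**
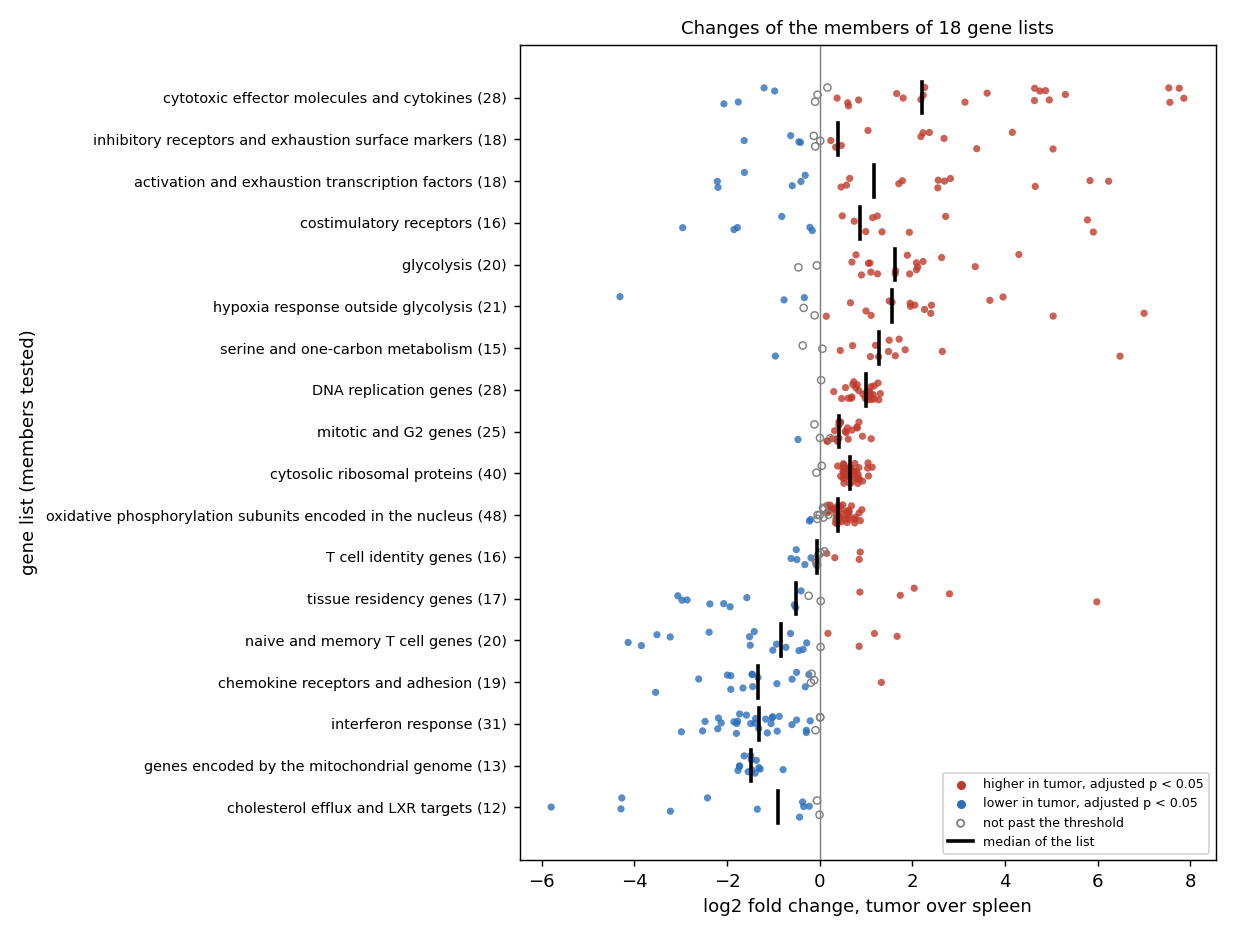
Log2 fold change (tumor over spleen) of each tested member of 18 gene lists, with 1 point per gene, filled where the adjusted p passed 0.05, and a bar at the median of the list. Cytotoxic effector genes have a median of 2.21 and glycolysis genes of 1.63, while interferon response genes (-1.31) and genes of the mitochondrial genome (-1.48) lie to the left of 0.

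Inhibitory receptors and exhaustion markers were higher in tumor for 11 of 18 genes and lower for 4, and 3 did not pass (list adjusted p = 1.0e-08). After Pdcd1 (32.8-fold), the largest rises were in Havcr2, which encodes TIM-3 (17.9-fold, log2 4.16, SE 0.08), Lag3 (10.5-fold), Pdcd1lg2, a ligand of PD-1 (6.43-fold), Tigit (5.16-fold) and Ctla4 (4.70-fold). Without tumor replicate 2 or spleen replicate 3, 9 of the 18 genes were higher. Cd101 (0.24) and Nt5e (0.35) lost their calls in both fits (adjusted p from 0.060 to 0.091), and Cd101 with upper-quartile scaling too (adjusted p = 0.054). Cd38, an ectoenzyme, fell by 1.63 on the log2 scale, and Btla (-0.63), Vsir (-0.41) and Cd200r1 (-0.45) were lower as well. The call of Cd200r1 was lost without spleen replicate 2 (adjusted p = 0.096) and without spleen replicate 3 (adjusted p = 0.053), and after the added correction for GC content and length (adjusted p = 0.071). Entpd1, which encodes CD39, was at 20.8 ± 0.65 CPM in tumor and 22.7 ± 0.935 CPM in spleen and did not pass (adjusted p = 0.26), nor did Cd244a (-0.13) and Cd274 (0.01). B cell markers (16 of 16) and macrophage markers (19 of 20) were lower in the same libraries. Any RNA of other cells in spleen was not separated from that of P14 cells. The falls and unchanged levels in this list may therefore not be those of P14 cells alone.

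Activation and exhaustion transcription factors rose for 12 of 18 genes and fell for 6 (list adjusted p = 2.8e-11). The NR4A genes, nuclear receptors induced by antigen receptor signalling, changed most, with log2 fold changes of 6.24 for Nr4a2, 5.84 for Nr4a3 and 4.65 for Nr4a1 (SE 0.09, 0.16 and 0.07). Egr2 (2.82), Egr3 (2.70), Irf4 (2.56) and Bhlhe40 (2.55) rose as well. Of the immediate early and heat shock genes that tissue dissociation can induce, 16 of 25 rose in the same libraries. These were 9 of 9 heat shock genes and 7 of 16 immediate early genes, of which 6 others fell. Tox, a regulator of exhausted T cells, rose by less, from 15.8 ± 1.01 to 24.2 ± 1.11 CPM (1.57-fold, adjusted p = 2.5e-05), and its relative Tox2 was lower (-2.19) at under 2 CPM in both tissues. Id2, an inhibitor of DNA-binding proteins (-1.62), Maf (-2.21), the T-bet gene Tbx21 (-0.59), Batf (-0.40) and Eomes (-0.31) were the other lower members. Markers of B cells (16 of 16) and macrophages (19 of 20) were lower in the same libraries, so the falls may not be those of P14 cells alone. The Eomes call was lost with the spleen libraries summed into 1 sample, an alternative added after seeing the data (adjusted p = 0.088).

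Costimulatory receptors were higher for 10 of 16 genes and lower for 6 (list adjusted p = 2.0e-06). Tnfrsf9, which encodes 4-1BB, was at 879 ± 13.2 CPM in tumor and 14.9 ± 0.591 CPM in spleen (60.0-fold), and Tnfrsf4, which encodes OX40, rose 55.0-fold. Tnfrsf25, the death receptor 3 gene (-2.96), and Cd86 (-1.85), which antigen-presenting cells also express, fell. Dendritic cell and MHC class II genes, 14 of 15, and B cell genes, 16 of 16, were lower in the same libraries. Cytokine receptors gave no list call (adjusted p = 0.64), with 6 of 20 higher and 10 lower. The median of that list was -0.22, while its mean (0.30) and its test pointed up. Il2ra, the high-affinity subunit of the IL-2 receptor, rose 6.36-fold and Il1r2, a decoy receptor for IL-1, 21.6-fold, while Tgfbr1 (-1.70) and Il27ra (-0.69) fell.

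Cytotoxic effector molecules and cytokines were higher for 21 of 28 genes and lower for 4 (median log2 fold change 2.21, list adjusted p = 1.3e-22). Ifng, the interferon gamma gene, was at 341 ± 34.6 CPM in tumor and 11.2 ± 0.477 CPM in spleen (31.1-fold). Granzyme B was abundant in both tissues, with Gzmb at 1776 ± 99.5 and 572 ± 9.18 CPM (3.17-fold). The perforin gene Prf1 rose 3.49-fold, Tnf 4.71-fold and Gzmc 29.3-fold. The 4 lower members were Ccl5, a chemokine (-1.76), Gzma (-1.20), Gzmm (-2.07) and the protease gene Ctsw (-0.97). Heat shock genes of the dissociation list rose in the same libraries, 9 of 9.

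**Figure D2:**
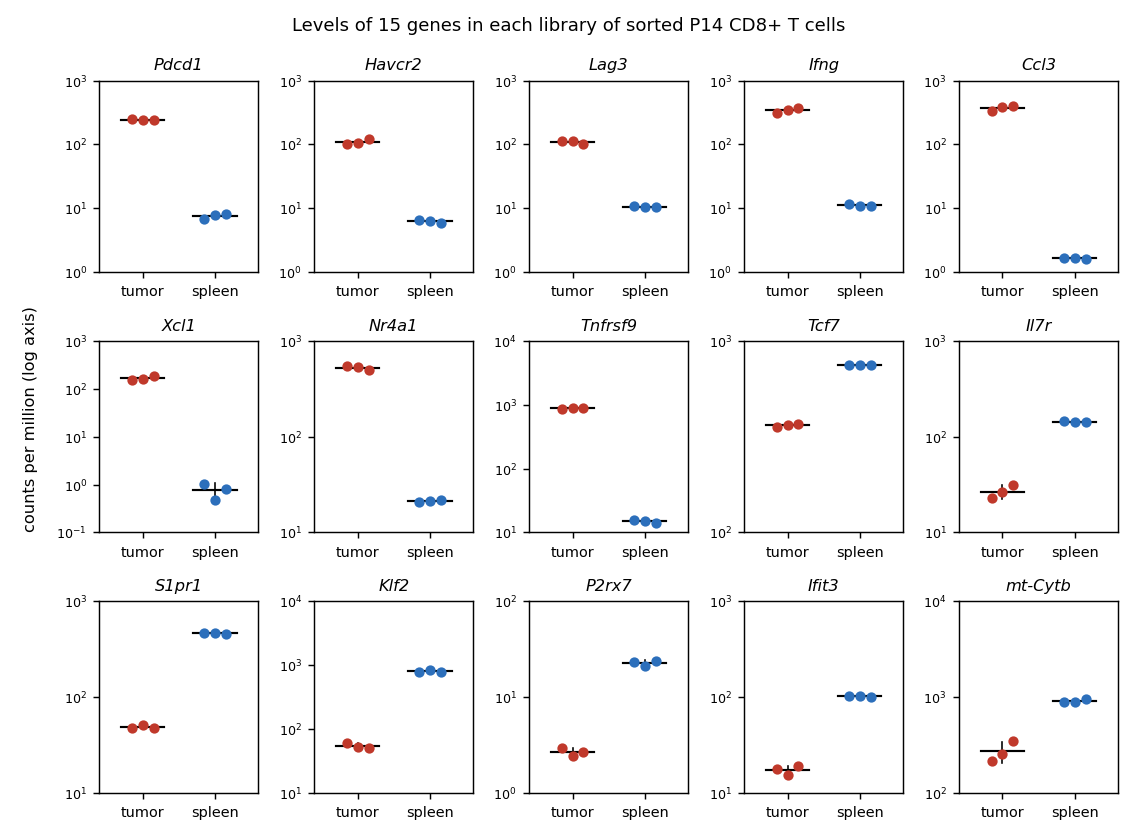
CPM on a log axis for 15 genes in the 3 tumor and 3 spleen libraries, with 1 point per library, a bar at the mean and a line of 1 SD. Tumor points lie above all spleen points for Pdcd1 (242 against 7.52 on average), Havcr2, Lag3, Ifng, Ccl3, Xcl1, Nr4a1 and Tnfrsf9, and below them for the other 7 genes, among them Klf2 (54.3 against 798).

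Naive and memory genes were lower in tumor for 15 of 20 and higher for 4 (list adjusted p = 5.6e-09). With an estimated correlation the list adjusted p was 0.046. B cell and myeloid markers were lower in the same libraries, 16 of 16 in the B cell list. Klf2, a transcription factor that maintains T cell circulation, fell by 3.85 on the log2 scale (SE 0.09), and its target S1pr1, the sphingosine receptor for exit into blood and lymph, fell by 3.22 (SE 0.06). Klf3 (-3.51), Il7r, the IL-7 receptor (-2.38), and Lef1 (-1.51) were lower too. Tcf7, which encodes TCF-1, was at 364 ± 6.37 CPM in tumor and 748 ± 1.97 CPM in spleen (2.02-fold lower). The 4 higher members were Myb (1.67), the lymph node homing receptor gene Ccr7 (1.18), Bach2 (0.85) and Satb1 (0.18). The Satb1 call was lost with the spleen libraries summed (adjusted p = 0.17).

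Chemokine receptors and adhesion genes were lower for 15 of 19, and 1, the integrin gene Itgav (1.33), was higher (list adjusted p = 2.0e-06). With an estimated correlation the list adjusted p was 0.046. Markers of B cells (16 of 16) and macrophages (19 of 20) were lower in the same libraries. Itgb1 (-1.65) and Cxcr3, a receptor for interferon-induced chemokines (-1.46), were among the lower members. Tissue residency genes gave no list call (adjusted p = 0.55), with 5 of 17 higher and 10 lower. The chemokine receptor gene Ccr8 rose 63.3-fold and Litaf 4.11-fold, and the other 3 higher members were Rgs1 (2.80), Rgs2 (1.74) and Ahr (0.87). P2rx7, a receptor for extracellular ATP, was 8.35-fold lower and Itga1, which encodes CD49a, 3.82-fold lower. Itgae, which encodes CD103 and was singled out after its values were seen, was lower too (-2.97). Killer cell receptors gave no list call either (adjusted p = 0.42), with 7 of 13 higher, among them the NKG2A gene Klrc1 (1.0) and Klri2 (2.91). Only 4 were higher without spleen replicate 2 or 3, and also with the spleen libraries summed. The lower members were Fcgr2b, an inhibitory Fc receptor (-2.78), Klrb1f (-0.63) and Klrg1 (-0.52). The Klrb1f call was lost in 4 of the 6 fits that left out 1 library (tumor replicate 1 or 2, spleen replicate 1 or 2), with adjusted p from 0.062 to 0.11, and the Klrg1 call without tumor replicate 1 or 3 or spleen replicate 3 (adjusted p from 0.090 to 0.21). With a replicate block, limma-voom or DESeq2 the Klrg1 call was lost too (adjusted p from 0.059 to 0.088).

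DNA replication genes rose together, 27 of 28, with 0 lower (median log2 fold change 1.0, list adjusted p = 1.2e-10). Mcm6, a subunit of the replicative helicase, was at 608 ± 17.6 CPM in tumor and 290 ± 3.91 CPM in spleen, and Dut, a dUTPase, rose 2.40-fold. Ccne2, a cyclin gene, did not pass (0.03), except without tumor replicate 1 (0.26, adjusted p = 0.044) and after the added correction for GC content and length (0.41, adjusted p = 0.0016). Mitotic genes rose by less, 21 of 25, with a median of 0.42, and Anln, an actin-binding protein of cell division, was lower (-0.47; 2 genes lower without tumor replicate 3). Their list adjusted p was 0.0023, and the adjusted p was 0.18 with an estimated correlation. Among the mitotic genes that rose, Aurkb and Cdk1, kinases of mitosis, had log2 fold changes of 0.92 and 0.85. Cytosolic ribosomal proteins were higher for 38 of 40 genes, such as Rpl4 (0.84), with 0 lower (list adjusted p = 8.5e-09). After the added correction for GC content and length 37 were higher and 2 lower, among them Rps27 (-0.35, adjusted p = 0.00079). With an estimated correlation that list had an adjusted p of 0.24.

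Glycolysis genes were higher for 18 of 20 and lower for 0, with Hk1 (-0.06) and Pfkfb4 (-0.46) not passing (median log2 fold change 1.63, list adjusted p = 1.3e-22). With an estimated correlation, which was 0.44, the list adjusted p was 0.049. The lactate exporter gene Slc16a3 rose 19.7-fold and Tpi1, triosephosphate isomerase, 10.3-fold, from 85.8 ± 1.5 to 863 ± 10.3 CPM. Pfkfb4, a regulator of glycolytic flux, was lower under each of the 3 other scalings (adjusted p from 0.033 to 0.050) and without tumor replicate 2 (adjusted p = 0.0059), among other alternatives. Hypoxia response genes outside glycolysis were higher for 16 of 21 and lower for 3 (list adjusted p = 1.8e-10). Bnip3, a mitophagy receptor, rose 12.8-fold and Ndrg1 5.28-fold. The lower members were Bnip3l (-0.33), whose call was lost with the spleen libraries summed (adjusted p = 0.079), and Adm and Car9 (-0.77), both at about 1 CPM or less. The Car9 call was lost without tumor replicate 1 or 3 or spleen replicate 1 or 3 (adjusted p from 0.051 to 0.19), and with a replicate block, limma-voom or DESeq2 (adjusted p from 0.050 to 0.064). Adm had 2 counts over the tumor libraries, both in replicate 2, and 47 over spleen (23.8-fold lower, 95% counting interval 6.24 to 203), and was at least 10.4-fold lower without that replicate.

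Serine and one-carbon genes rose for 12 of 15, and 1 fell (list adjusted p = 1.8e-10, and adjusted p = 0.041 with an estimated correlation). Shmt1, a serine hydroxymethyltransferase, rose 6.27-fold and Psat1, of serine synthesis, 3.10-fold. Amino acid transporters were higher for 9 of 13, among them Slc7a1, for cationic amino acids (3.98-fold), and Slc3a2, the shared heavy chain of several transporters (3.22-fold). The 3 lower members were Slc43a2 (-0.93), Slc38a2 (-0.29) and Slc38a5, with 0 counts in tumor and at least 17.6-fold lower. The adjusted p of this list was 0.00075, and the adjusted p was 0.15 with an estimated correlation. Unfolded protein and integrated stress response genes were higher for 20 of 25 (list adjusted p = 5.8e-06), led by the transcription factor gene Atf3 (17.9-fold) and Asns, asparagine synthetase (16.6-fold). The 3 lower members, all chaperone or degradation factors of the endoplasmic reticulum, were Dnajb9 (-1.07), Dnajc3 (-0.58) and Herpud1 (-0.35). Redox defence genes were higher for 14 of 21 and lower for 5 (list adjusted p = 0.022, and adjusted p = 0.17 with an estimated correlation). The metallothionein genes Mt2 (31.9-fold) and Mt1 (18.9-fold) rose, while Hmox1, heme oxygenase (-2.80), Nfe2l2 (-0.83), Cat (-0.68), Nqo1 (-0.67) and Keap1 (-0.23) fell. Macrophage markers, 19 of 20, were lower in the same libraries. The Nqo1 call was lost without tumor replicate 1 or spleen replicate 1 (adjusted p of 0.072 and 0.093), with DESeq2 (0.074) and with the spleen libraries summed (0.11), and the Keap1 call with the spleen libraries summed (adjusted p = 0.12). In the list of immediate early and heat shock genes, which tissue dissociation can induce, 16 of 25 rose and 6 fell (list adjusted p = 2.8e-07). Its 9 heat shock members rose with a median of 1.66, whereas of its 16 immediate early members 7 rose and 6 fell, including Socs3 (-1.64) and Zfp36 (-0.83).

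Nuclear genes of oxidative phosphorylation were higher in tumor for 39 of 48, including Atp5b, a subunit of ATP synthase (0.91, SE 0.05), and Uqcrq, of complex III (0.76). Their median was 0.40, with a list adjusted p of 0.00029 and an adjusted p of 0.19 with an estimated correlation. After the added correction for GC content and length 36 were higher and 4 lower, with a median of 0.31. Before it, the 2 lower members were the complex I genes Ndufb10 (-0.22) and Ndufa1 (-0.20). Their calls were lost in several fits that left out 1 library: for Ndufb10 without tumor replicate 2 (adjusted p = 0.068) or spleen replicate 1 (adjusted p = 0.051), and for Ndufa1 without tumor replicate 1 or 2 or spleen replicate 1 or 3 (adjusted p from 0.065 to 0.15) and with no low-count filter (adjusted p = 0.062). All 13 protein genes of the mitochondrial genome were lower, with a median of -1.48 (list adjusted p = 0.0011, and adjusted p = 0.39 with an estimated correlation). The cytochrome b gene mt-Cytb was at 272 ± 67.7 CPM in tumor and 916 ± 44.7 CPM in spleen, and mt-Nd4l at 16 ± 3.6 and 42.8 ± 3.01 CPM. TCA cycle genes were higher for 17 of 23 and lower for 0 (1 lower without tumor replicate 3), for instance Mdh2, malate dehydrogenase (0.88), and Dlat (0.79). That list had an adjusted p of 0.023, and an adjusted p of 0.11 with an estimated correlation. Fatty acid oxidation genes gave no list call (adjusted p = 0.36), with 8 of 20 higher, such as Acot7 (0.89), and 4 lower. The lower genes were Cpt1a, which controls fatty acid entry into mitochondria (-0.77), Acadm (-0.38), Hadh (-0.22) and Hadhb (-0.21). The Hadh call was lost without spleen replicate 2 (adjusted p = 0.070), and Hadhb stood at 0.046 and did not pass after the added correction for GC content and length (adjusted p = 0.47).

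Cholesterol synthesis genes were higher for 13 of 23 and lower for 1, Mvd (-0.63). Ebp was called lower too when scaled by upper quartile (adjusted p = 0.018) or library size (adjusted p = 0.031) and at a mean of at least 5 CPM (adjusted p = 0.014). Sqle, squalene epoxidase, rose 2.83-fold (list adjusted p = 0.024, and adjusted p = 0.11 with an estimated correlation). Cholesterol efflux genes and LXR targets were lower for 10 of 12 and higher for 0 (list adjusted p = 2.0e-06). Nr1h3, which encodes LXR alpha, was 19.3-fold lower and the cholesterol exporter gene Abcg1 5.35-fold lower. Macrophage markers, 19 of 20, were lower in the same libraries, and Apoe (-4.29) belongs to both lists. Fatty acid synthesis, uptake and storage genes went both ways, with 13 of 25 higher and 9 lower and no list call (adjusted p = 0.60; median 0.25, mean -0.03, test up). Fabp5, a fatty acid carrier, rose 3.56-fold and Dgat1, of triglyceride synthesis, 2.55-fold, while the scavenger receptor gene Cd36 was 10.6-fold lower and the desaturase gene Scd1 8.15-fold lower.

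Interferon response genes were lower in tumor for 28 of 31 and higher for 0 (median -1.31, list adjusted p = 3.7e-16). Ifit3 was at 17.4 ± 1.82 CPM in tumor and 102 ± 1.38 CPM in spleen (5.76-fold lower), and Irf7, a transcription factor of the type I interferon response, was 3.47-fold lower. Psmb8 (0.01) and Gbp3 (0.01), both induced by interferon gamma, did not pass, nor did Psmb9 (-0.09), which passed when scaled by upper quartile (adjusted p = 0.033) or library size (adjusted p = 0.043) and at a mean of at least 5 CPM (adjusted p = 0.023). B cell and myeloid markers were lower in the same tumor libraries.

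Markers of other cell types differed mainly through their level in spleen. B and plasma cell genes were lower in tumor for 16 of 16 (median -8.52, list adjusted p = 2.5e-78). Igkc, the kappa light chain, was at 0.805 ± 0.141 CPM in tumor and 353 ± 7.16 CPM in spleen. Ighm, the mu heavy chain, changed least in that list, from 807 ± 8.11 CPM in spleen to 270 ± 1.70 CPM in tumor. Dendritic cell and MHC class II genes were lower for 14 of 15 (list adjusted p = 3.2e-25), among them Cd74, the invariant chain, at 19.2 ± 0.746 and 1012 ± 18 CPM, and the exception was Ccr7. Their median was -4.92, or -4.39 with genes at 0 set to their bound. Macrophage and monocyte genes were lower for 19 of 20, for example the complement gene C1qc (-4.85) and Lyz2, lysozyme (-3.13), and Arg1, arginase, was higher (2.68) at under 1 CPM (list adjusted p = 2.3e-21). Neutrophil and mast cell genes were lower for 10 of 10, such as S100a8 (-6.44) and S100a9 (-6.19), with a list adjusted p of 2.0e-06 and a median of -6.23, or -5.23 with genes at 0 set to their bound.

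Erythroid and platelet genes went both ways, with 7 of 12 lower and 5 higher (list adjusted p = 0.013, and adjusted p = 0.26 with an estimated correlation). Carbonic anhydrase 2, Car2 (-2.58), and the platelet integrin gene Itga2b (-4.72) were lower, and the higher members were the hemoglobin genes Hbb-bs (0.49), Hbb-bt (0.43), Hba-a2 (0.30) and Hba-a1 (0.29) and the heme synthesis gene Alas2 (0.65). At a mean of at least 5 CPM, 5 of its members were tested, with 4 higher and 1 lower and no list call (median 0.25, adjusted p = 0.84), against a median of -3.43 over the 12. Without tumor replicate 3 the adjusted p of this list was 0.089, and the Hba-a1 and Hba-a2 calls were lost after the added correction for GC content and length (adjusted p of 0.56 and 0.15). Hemoglobin genes come in near-identical copies, and their separate values are uncertain. Genes of CD4, regulatory and gamma-delta T cells gave no list call (adjusted p = 0.060), with 6 of 9 lower, including Cd4 (-2.77) and Trdc (-0.87), and 1 higher, Ikzf4 (1.57; 2 higher without tumor replicate 1 or spleen replicate 2). The list was called lower without tumor replicate 3 (adjusted p = 0.037), with no low-count filter (0.028), after the added correction for GC content and length (0.043) and by fry (5.0e-05). NK and innate lymphoid genes were higher for 5 of 12 and lower for 5 (adjusted p = 0.31, median 0.09, mean 0.24, test down), and at a mean of at least 5 CPM the list was called lower (adjusted p = 0.0055). The median of the NK list was -0.24 without tumor replicate 3, and 0.29 and 0.22 without tumor replicates 1 and 2. In that list Cd7 was 6.31-fold lower and Kit, a growth factor receptor, 2.77-fold higher. Of 6 fibroblast and endothelial genes, 4 were lower and Acta2 (0.62) was higher, with no list call (adjusted p = 0.21). The endothelial adhesion gene Pecam1 was at 54.8 ± 2.29 CPM in tumor and 86.2 ± 0.932 CPM in spleen. Only 5 of 15 melanocyte genes had counts enough to test, with no list call (adjusted p = 0.78; median -0.05, mean 1.28, test up). The median depends on few genes: with 6 tested it was 1.51 without tumor replicate 3 and 1.57, 1.37 and 1.6 without spleen replicate 1, 2 or 3. With no low-count filter 6 of 13 were higher, again without a list call. Trpm1 (3.06) was higher in tumor at 1.68 ± 0.121 CPM, and Dct was higher at 0.460 ± 0.018 CPM. Pmel was lower (-1.18). Dct had 51 counts over the tumor libraries and 1 over spleen (50.3-fold, 95% counting interval 8.62 to 2024), and was at least 11.0-fold higher without spleen replicate 2, which held that count.

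**Figure D3:**
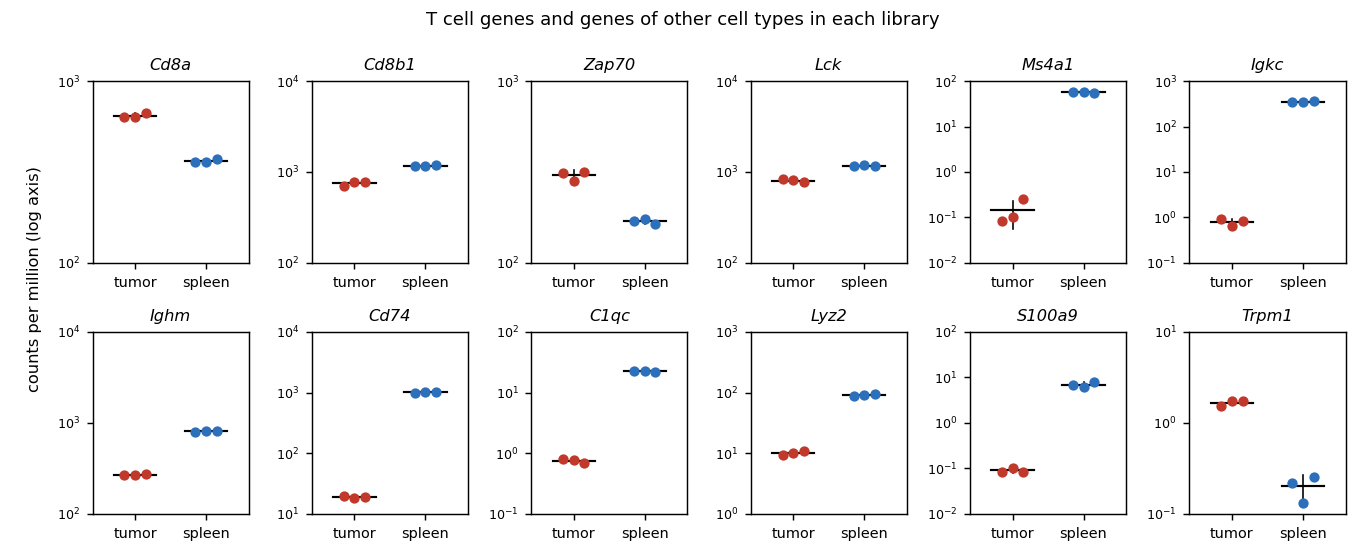
CPM on a log axis for T cell genes and genes of other cell types in the 3 tumor and 3 spleen libraries, with 1 point per library, a bar at the mean and a line of 1 SD. Spleen points lie above tumor points for the B cell and myeloid genes (Igkc at 353 against 0.805 CPM on average) and below them for Cd8a, Zap70 and Trpm1.

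T cell identity genes gave no list call (adjusted p = 0.94), with 4 of 16 higher, 5 lower and 7 not passing (median -0.06, mean -0.01, test up). With upper-quartile scaling, and at a mean of at least 5 CPM, 3 were higher and 8 lower. After the added correction for GC content and length 5 were higher and 8 lower. Cd3e, a chain of CD3 singled out after its values were seen, was at -0.06 and did not pass, though it did with upper-quartile scaling (-0.12, adjusted p = 0.044) and at a mean of at least 5 CPM (-0.11, adjusted p = 0.033). The genes of the CD8 chains moved apart, with Cd8a higher (0.85) and Cd8b1 lower (-0.62). Zap70, a kinase of receptor signalling, was higher (0.88) and the kinase gene Lck lower (-0.50). The V segment genes related to the P14 receptor were lower for 12 of 12, such as Trbv13-3 (-0.95) and Trav14-1 (-0.57), with a list adjusted p of 0.024 and an adjusted p of 0.42 with an estimated correlation. These segments are members of families with near-identical copies, and their separate values are uncertain.

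The make-up of the libraries differed between tissues as well. Mitochondrially encoded genes took 0.412 ± 0.0858% of counts in tumor and 1.13 ± 0.0467% in spleen. Ribosomal protein genes took 2.45 ± 0.042% and 1.65 ± 0.0753%, and the 10 most abundant genes 5.77 ± 0.511% and 6.93 ± 0.0663%. Genes with at least 1 count numbered 26311 ± 150.4 in tumor and 28505 ± 242 in spleen. For each of these 4 measures the tissues did not overlap (two-sided exact permutation p = 0.1, n = 3 per tissue, the smallest this design allows).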

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

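The summed spleen libraries, the GC and length correction and the weight per tissue were chosen after the results were seen. Leaving out 1 library gave 6349 to 7191 higher genes, 6549 to 7518 lower genes and 17 higher and 11 lower lists. Counts within 1.5 times the main ones came from every other scaling, filter and tool. They ran from 4863 higher and 4818 lower (mean of at least 5 CPM, 12595 genes tested) to 7398 and 7972 (no filter, 35231 genes tested). The tighter spleen libraries, summed into 1 sample, left 5104 and 5349. The GC and length correction gave 7239 and 7381, with 4 calls in the opposite direction. Counts moved further in these cases: the 2-fold null left 1161 higher and 1864 lower genes, since smaller changes cannot pass it, and the estimated correlation left 10 higher lists. For named genes, 4275 values under alternatives kept their side of the threshold, 141 lost the call and 22 gained it. In 1 more, a called gene changed sign: Hadhb, at 0.046 after the GC and length correction. A change of sign was counted only where the main fit or the alternative passed, so the 4275 can include others. For single lists, 540 values kept their side under the same rule, 16 lost the call and 11 gained it. At a mean of at least 5 CPM, 5 lists lost their calls: TCA, cholesterol synthesis, redox, P14 segments and erythroid (adjusted p of 0.092, 0.092, 0.066, 0.11 and 0.84). The median of the last went from -3.43 to 0.25, with 5 of 12 members tested. The neutrophil and mast cell list had no member to test there. The NK list was called lower there (adjusted p = 0.0055). Summing the spleen libraries also ended the calls of Bcl2, Car9, Cd101, Cd200r1, Hadh, Hadhb, Hba-a1, Hba-a2, Il2, Klrb1f, Klrg1, Ndufa1, Ndufb10 and Nt5e. The weight per tissue ended those of Car9 and Klrg1 (adjusted p of 0.099 and 0.10). Apart from the 2-fold null, the cause of these changes was not tested. A replicate block gave 6746 higher and 7026 lower genes. Of the named results, it changed the calls of Car9, Klrg1 and Pfkfb4 (adjusted p of 0.050, 0.061 and 0.020) and no other. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. With edgeR, the real split gave 6890 higher and 7093 lower genes, and the highest other split 0 of each. Every other split mixes the tissues, so the tissue difference widens the spread within its groups. Gene and list counts of the other splits are therefore no measure of what chance gives. The other splits had 16 to 71 genes at an unadjusted p under 0.05. The real split gave 17 higher lists (highest other 13) and 11 lower (highest other 13), and 1, 1, 1 and 6 of the 10 splits reached these 4 values, taking the larger direction of each other split, since a split and its mirror are 1. At this depth and spread, 21.0% of the smallest simulated changes passed.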

Other observations

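The tests on other cell types, the gene ratios and the choice of the patterns were chosen only after the results were seen. The correction for GC content and length was added after the first results, but its expected outcome, like that for single libraries, was set before its own result.

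The ratio of Cd8a to Cd8b1 counts was 0.860 ± 0.0431 in tumor and 0.310 ± 0.00313 in spleen (SD, n = 3 each), and was higher in all 3 tumor libraries than in any spleen library (two-sided exact permutation p = 0.1, the smallest this design allows). The 2 genes encode the chains of the CD8 coreceptor, which T cells carry as an alpha-beta pair or as alpha alone. Ighm stood apart from Igkc, a light chain gene. Its counts were 343 ± 63.3 times those of Igkc in tumor and 2.29 ± 0.0268 times in spleen, with the same exact permutation p = 0.1, so that Ighm RNA in tumor libraries was not matched by Igkc RNA. No ratio to other light chain genes was taken. Counts of several melanocyte genes too low to test lay mostly in the tumor libraries, with 64 counts of Tyrp1 over the 3 tumor libraries and 0 over spleen, 19 and 2 of Mlana, 16 and 2 of Sox10 and 5 and 2 of Tyr. These genes, singled out after their values were seen, encode enzymes, an antigen and a transcription factor of pigment cells.

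B cell and myeloid genes were higher in the spleen libraries. A candidate explanation is RNA from other cell types in those libraries, although the cells were sorted as donor P14 cells. All 16 tested B and plasma cell genes, none of which is in another list, were lower in tumor, but this restates the pattern and cannot support that explanation. The most abundant were Ighm (807 CPM in spleen) and Igkc (353 CPM). A lower T cell share that raises all other types alike was examined by comparing lists. The median log2 fold change was -8.52 (SD 2.66) over the 16 genes of the B cell list and -3.60 (SD 2.28) over the 20 of the macrophage list, 4.92 apart. A high level in tumor can hide part of such a rise, and with the 8 macrophage genes at 1 CPM or more in tumor set to the B cell median the lists were still 2.999 apart. Each fold also depends on the abundance of the gene in spleen and on the few counts left in tumor. Unequal medians therefore cannot decide on the T cell share. T cell identity genes showed no common shift, with 4 of 16 higher in tumor, 5 lower and a median of -0.06. Their log2 fold changes ranged from -0.62 to 0.88, so a small difference in share would not show in them. Which cells or free RNA carried these transcripts, and a difference between spleen and tumor P14 cells themselves, stay open.

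Interferon response genes were lower in tumor for 28 members. After correction for GC content and exonic length 28 members were lower, which argues against that bias as the whole cause. Other cells in the spleen libraries could raise these genes, but would have to supply a median of 59.8% of their spleen level. No library of those cells was analysed here, so their part cannot be told apart from a lower response in tumor P14 cells. That biological difference between the tissues stays open and untested.

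Mitochondrially encoded genes were lower in tumor, 13 of 13, while 39 of 48 nuclear genes of oxidative phosphorylation were higher and 2 lower. After correction for GC content and length, 36 of these 48 nuclear genes were higher and 4 lower. With an estimated correlation neither list was called (adjusted p of 0.39 and 0.19). Correction for GC content and length left the median of the 13 genes at -1.36, against -1.48 before, which argues against that trend as the whole cause. With any 1 tumor library left out, at least 13 of 13 genes were called lower, which argues against a single library. Tissue handling, which by the labels' protocols differed by at least the Percoll step, is confounded with tissue and stays open beside a biological difference in mitochondrial transcripts, which may account for the fall and was not tested.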
